A study of Mus musculus with 13 samples.

How the data were processed

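Polyadenylated RNA from 13 mouse livers was sequenced in 4 groups: control vehicle (3), Hnf4aLKO vehicle (3), control tunicamycin (4) and Hnf4aLKO tunicamycin (3). Per the labels' protocols, male mice with floxed Hnf4a alleles on a C57BL/6J background, 8 to 12 weeks old, received the virus, were fasted for 4 h 1 week later, were injected with 0.5 mg/kg tunicamycin or vehicle, and were sampled at 14 h. The series design states 3 to 4 mice per group, and each library was taken as 1 mouse.

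Per the submitters' processing notes, reads were checked with FastQC 0.11.8 and kallisto 0.45.0 and DESeq2 were used with the mouse genome GRCm38 (mm10). The notes give neither the DESeq2 version nor the release of the transcript annotation. The deposited file of each library holds the estimated count per transcript, per the file headers, beside transcript length and effective length. The authors also deposited a normalized signal table with 1 value per gene and library, used here only as an alternative. Its columns could be matched to groups but not to single libraries, its values lie near the summed estimated counts times a factor that varies by gene, and some of its gene names had been turned into dates.

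Estimated counts were summed per gene with the GENCODE M21 annotation of GRCm38 and rounded. Of 115270 transcripts, 113580 matched 35580 genes, and the 1690 without a match, with 0.57% to 3.23% of the counts of a library, were left out. Library totals were 15.13 to 22.26 M. TPM values were computed here from the estimated counts and effective lengths.

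The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 on all 13 libraries in 1 fit with a mean per group, TMM scaling, the filter filterByExpr (13292 genes kept) and Benjamini-Hochberg adjustment, with adjusted p under 0.05 called changed. The 5 contrasts were deletion under vehicle, tunicamycin in control mice, tunicamycin in Hnf4aLKO mice, deletion under tunicamycin, and the interaction, which is tunicamycin in Hnf4aLKO minus tunicamycin in control mice. Standard errors of log2 fold changes are the log2 fold change over the square root of F from the same fit. Fold changes against a group with 0 counts are given as lower bounds with a floor of 3 counts over the group, and those against 1 to 3 counts as ratios with a 95% interval; these bounds and intervals cover counting error only.

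The 39 gene lists were written before the data were examined: ER chaperones; ER-associated degradation; ER translocation, glycosylation and transport; the PERK-ATF4-CHOP arm; ATF4-regulated amino acid genes; hepatocyte transcription factors; apolipoproteins and lipoprotein assembly; bile acids; fatty acid oxidation; lipogenesis; cholesterol synthesis; gluconeogenesis; urea cycle and amino acid breakdown. Further lists were coagulation, complement, acute phase, phase 1 drug metabolism, glutathione conjugation and NRF2 targets, male-biased, female-biased, pericentral, periportal, cell cycle, fetal and dedifferentiation, p53 and cell death, clock, nuclear respiratory chain, mitochondrially encoded and ribosomal protein genes. Cell type lists covered Kupffer cells and macrophages, neutrophils, T and NK cells, B cells, endothelium, stellate cells, bile duct, erythroid cells, pancreas and fat, and hepatocytes. The 38 lists with at least 5 tested members were tested with camera of limma 3.58.1 on voom values with a preset correlation of 0.01, again with a correlation estimated from the data, and with fry, each adjusted over the lists of a contrast. Camera compares a list with all other genes. Fry tests whether a list moves on balance one way and does not compare it with other genes.

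The genes named in the text follow a rule fixed before the data were examined: the 10 genes with the largest rise and the 10 with the largest fall among called genes with at least 5 CPM in the higher group whose libraries of one group all lay above those of the other (without unnamed genes; for the interaction, the 10 largest in each direction), 20 genes chosen in advance, and up to 4 called members of each list with the largest change, or the 2 most abundant where edgeR called 0.

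Each step was tested on simulated counts (negative binomial) drawn from the means and depths of the real libraries, with 200 genes changed, 50 at each fold. Of genes changed 2-fold, edgeR recovered 44% for deletion under vehicle (12778 genes tested), 48% for tunicamycin in control mice (12691), 36% for tunicamycin in Hnf4aLKO mice (12730), 44% for deletion under tunicamycin (12701) and 36% for the interaction (12670). At 4-fold the shares were 78%, 82%, 82%, 84% and 74%, and 3, 2, 3, 2 and 6 unchanged genes were called.

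Alternatives fixed in advance were RLE and upper-quartile scaling, no filter and a filter of at least 10 counts in every library of a group, DESeq2 1.42.0, limma-voom, a transcript length offset, a fit of the compared groups only, adjusted p under 0.01, a fold threshold of 1.5 (glmTreat), limma on the authors' table and on TPM (log2 with 1 added), and leaving out each library in turn. Limma-voom with sample quality weights and the removal of the 2 control libraries with the most major urinary protein counts were added after seeing the data. The slope of the tunicamycin response between genotypes was the major axis through the origin, and 20 simulations with equal responses gave its chance range. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for reading and drawing.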

Results

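Messenger RNA was sequenced from the livers of 13 male mice that carried floxed alleles of Hnf4a, the gene of hepatocyte nuclear factor 4 alpha, a nuclear receptor that drives the hepatocyte programme. An adeno-associated virus with the hepatocyte-specific TBG promoter delivered Cre recombinase (Hnf4aLKO mice) or green fluorescent protein (control mice). Mice were injected 1 week later with vehicle or with 0.5 mg/kg tunicamycin, which blocks N-glycosylation and so causes stress of the endoplasmic reticulum (ER), and livers were taken after 14 h. The groups held 3 control vehicle, 3 Hnf4aLKO vehicle, 4 control tunicamycin and 3 Hnf4aLKO tunicamycin mice. The series title asks how a disturbed HNF4 network bears on ER stress in hepatocytes, and the design gives the effect of deletion with and without tunicamycin, the effect of tunicamycin in each genotype, and their interaction. Library totals were 19.04 to 19.78 M estimated counts in control vehicle, 19.74 to 20.75 M in Hnf4aLKO vehicle, 20.59 to 22.26 M in control tunicamycin and 15.13 to 19.06 M in Hnf4aLKO tunicamycin mice. All values below are mean CPM (counts scaled to library size) ± SD or log2 fold changes ± SE, and adjusted p-values of single genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

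Hnf4a (ENSMUSG00000017950, chromosome 2, 163506808 to 163572910, plus strand, GRCm38) was measured in every library. Control vehicle replicates 1, 2 and 3 had 535, 623 and 402 CPM, and Hnf4aLKO vehicle replicates 1, 2 and 3 had 406, 287 and 276. Control tunicamycin libraries had 565 to 803 and Hnf4aLKO tunicamycin libraries 155 to 175 CPM. Hnf4a was lower in Hnf4aLKO mice under vehicle (log2 fold change -0.69 ± 0.21, edgeR adjusted p = 0.0272), although Hnf4aLKO vehicle replicate 1 lay above control vehicle replicate 3. This call ended without control vehicle replicate 1 (-0.67, adjusted p = 0.055) or 2 (-0.49, adjusted p = 0.128) and without Hnf4aLKO vehicle replicate 2 (-0.57, adjusted p = 0.128) or 3 (-0.58, adjusted p = 0.108). The adjusted p ran from 0.00337 to 0.814 over all alternatives, the highest on the TPM scale. Under tunicamycin the difference was larger (-2.00 ± 0.21, edgeR adjusted p = 9.95e-06), and every Hnf4aLKO library lay below every control library. The floxed exons are not given in the sources used here. The most abundant transcripts, Hnf4a-201 and Hnf4a-202, both have 10 exons, and counts over the whole gene do not separate transcripts of intact and recombined alleles.

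**Figure D1:**
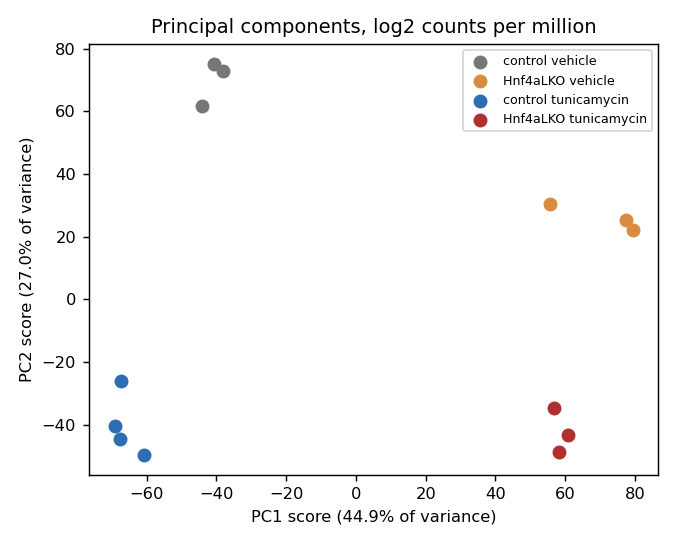
Scores of the 13 libraries on the first 2 principal components of log2 CPM, with 1 point per library and colours for the 4 groups. Component 1 (44.9% of the variance) places all Hnf4aLKO libraries between 55.5 and 79.3 and all control libraries between -69.2 and -38, and component 2 (27%) places tunicamycin libraries below and vehicle libraries above 0.

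Under vehicle, livers of Hnf4aLKO mice had lower levels of genes for drug metabolism, lipoprotein assembly and the male liver programme, and of some bile acid genes, and higher levels of p53 targets and cell cycle genes. Cyp8b1, which makes cholic acid, fell from 434 ± 141 to 2.18 ± 1.84 CPM (n = 3 each, log2 fold change -7.61 ± 0.59, edgeR adjusted p = 1.31e-06). The steroid and xenobiotic enzymes Cyp2c54 (-8.69), Cyp2c50 (-8.05) and Cyp2c40 (-6.95), the male-specific steroid enzyme Hsd3b5 (-8.21), the carboxylesterase Ces3b (-6.99) and the acute-phase gene Saa1 (-8.37) were among the 10 genes that fell most, with Lrit1 (-7.43), Extl1 (-7.08) and C1rb (-8.14). Members of the Cyp2c, Ces and Saa families share reads, so their single levels are uncertain. The size of the Saa1 fall rests on control vehicle replicates 2 and 3. It had 33.5, 1403 and 4459 CPM in control vehicle replicates 1, 2 and 3 and 2.02 to 11.79 in Hnf4aLKO vehicle libraries. C1rb and its near-identical copy C1ra traded counts between libraries. Their sum was 321 ± 26.6 CPM in control vehicle and 171 ± 29.2 in Hnf4aLKO vehicle mice, against 222 ± 64.6 and 0.764 ± 0.339 for C1rb alone. The C1rb call ended in limma-voom (adjusted p = 0.0735, range over alternatives 7.38e-08 to 0.0735).

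The genes that rose most under vehicle were near absent from control livers. The potassium channel gene Kcnk16 was at least 118-fold higher (3 counts as floor over the group). Pnliprp1, a pancreatic lipase-related gene, had 48.5 ± 23.5 CPM in Hnf4aLKO and 3 counts in total in control livers, a ratio of 745 (95% counting interval 255 to 3620). Sorcs2 (ratio 801, 274 to 3890), the insulin-responsive glucose transporter gene Slc2a4 (165, 56.1 to 801) and Psrc1 (167, 45.9 to 1380) followed, with Epdr1 (log2 fold change 6.55 ± 0.65) and Cox6b2 (6.41 ± 0.49). The amylase copies Amy2a2, Amy2a3 and Amy2a4 carried identical estimated counts, so which copy rose is uncertain. Each was at least 104-fold higher, and this call ended in limma-voom (adjusted p = 0.0928, range over alternatives 4.12e-07 to 0.0928). The acinar genes Cpa1, Cpb1, Pnlip, Ctrb1 and Clps had at most 8 counts in any group. Of 5 measured pancreas and fat markers, 2 rose, led by Cela3b (at least 20.2-fold) and Cela2a (2.17 ± 0.55), and 1 fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.282).

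In all, 3903 of 13292 tested genes (29.4%) differed under vehicle, 1702 higher and 2201 lower, and 879 and 1201 of them by at least 2-fold. In 3677 of the called genes every library of one genotype lay above every library of the other. Chance gives this separation to 10% of unchanged genes, but a call itself favours separated genes, so the count is no independent support. The rising share was 43.6%. It was 63.7% with upper-quartile scaling, which moved the median of all genes by 0.19, and 86.1% on the TPM scale, which moved it by 0.39. Directions of gene groups were checked under each scaling. On the TPM scale some medians came near 0: hepatocyte transcription factors went from -0.53 to 0 and bile acid genes from -0.58 to -0.02. Mitochondrially encoded genes went from -0.71 to -0.13, coagulation from -0.80 to -0.16 and urea cycle genes from -0.96 to -0.19. Lipoprotein genes kept a median of -1.17 and male-biased genes of -2.74 on that scale. Of 38 tested lists, camera called 22. With an estimated correlation between genes it called 0 (5 at an unadjusted p under 0.05), and fry, which tests whether the genes of a list move on balance one way, called 22.

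Lipoprotein and cholesterol synthesis genes fell, while other lipid genes moved both ways. Of 22 measured genes of apolipoproteins and lipoprotein assembly, 15 fell and 7 did not pass (17 lower and 3 higher adjusted over the list alone; camera adjusted p = 9.62e-08, adjusted p = 0.076 with an estimated correlation). Apoa2 (-5.18 ± 0.41), the lipid transfer gene Cideb (-4.49 ± 0.36), hepatic lipase Lipc (-4.40 ± 0.38) and Apoa4 (-4.26 ± 0.89) changed most. Of 22 cholesterol synthesis genes 17 fell (20 adjusted over the list alone; camera adjusted p = 2.95e-07, adjusted p = 0.391 with an estimated correlation). Insig1 (-3.13 ± 0.37) was among them. The list mean (log2) was 6.69, 5.87 and 7.68 in control vehicle replicates 1, 2 and 3 and 4.96 to 5.47 in Hnf4aLKO vehicle libraries. Idi1 changed by -2.81, and by -1.75 without control vehicle replicate 3. Of 25 bile acid genes 11 fell and 5 rose, in both counts (camera adjusted p = 0.00388, adjusted p = 0.431 with an estimated correlation). After Cyp8b1 came the conjugating enzymes Baat (-6.02 ± 0.41) and Slc27a5 (-5.81 ± 0.43). Fatty acid oxidation split, 7 of 29 up and 7 down in both counts, from Pdk4 (4.65 ± 0.46) to Bdh1 (-4.15 ± 0.61). Its median was 0.04 and its mean -0.27, and camera did not call it (adjusted p = 0.828). Lipogenesis split as well, 8 of 27 up and 7 down (9 and 7 adjusted over the list alone; camera adjusted p = 0.828), from Cidea (4.58 ± 0.65) to Cidec (-2.96 ± 0.64; -1.53 without control vehicle replicate 2).

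Other hepatocyte functions were lower too. Of 24 phase 1 drug metabolism genes 14 fell and 3 rose (15 and 3 adjusted over the list alone; camera adjusted p = 6.36e-05, adjusted p = 0.31 with an estimated correlation). Of 20 genes that are higher in male than female liver 17 fell (18 adjusted over the list alone; median -3.18, camera adjusted p = 2.48e-11, adjusted p = 0.076 with an estimated correlation). Ugt2b1 (-5.49 ± 0.49) followed Hsd3b5. Of 16 female-biased genes 5 rose and 2 fell (6 and 2 adjusted over the list alone; camera adjusted p = 0.0185, adjusted p = 0.275 with an estimated correlation). Prom1 rose (4.70 ± 0.29), Cyp2c69 was at least 97.1-fold lower, and the list call ended without control vehicle replicate 3 (adjusted p = 0.104) and with no filter on low counts (0.128, the highest but for the estimated correlation). Of 19 complement genes 14 fell, C8a (-5.56 ± 0.61) and the lectin Mbl2 (-5.03 ± 0.61) most, and 1 rose (16 and 1 adjusted over the list alone; camera adjusted p = 2.38e-06, adjusted p = 0.307 with an estimated correlation). Of 23 coagulation genes 11 fell, F12 (-5.03 ± 0.43) and F13b (-4.51 ± 0.53) most, and 3 rose, in both counts (camera adjusted p = 0.00136, adjusted p = 0.431 with an estimated correlation).

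Of 24 hepatocyte transcription factor genes 10 fell and 1 rose (10 and 3 adjusted over the list alone; camera adjusted p = 0.0124, adjusted p = 0.487 with an estimated correlation), among them the xenobiotic receptor Nr1i3 (-5.56 ± 0.74), Ppara (-2.74 ± 0.24) and Cebpa (-1.87 ± 0.24). Of 25 urea cycle and amino acid breakdown genes 10 fell, led by Otc (-5.63 ± 0.72; 12 adjusted over the list alone; camera adjusted p = 0.00518, adjusted p = 0.616 with an estimated correlation), a call that ended without control vehicle replicate 2 (0.0884). Of 18 gluconeogenesis genes 8 fell, led by Pcx (-2.81 ± 0.18; 8 lower and 2 higher adjusted over the list alone; camera adjusted p = 0.0309, adjusted p = 0.487 with an estimated correlation), and the median of -0.59 turned to 0.09 on the TPM scale. Periportal genes fell in 6 of 21 cases, in both counts, led by Cyp2f2 (-5.24 ± 0.91; camera adjusted p = 0.00374, adjusted p = 0.431 with an estimated correlation). Clock genes fell in 9 of 18 (11 adjusted over the list alone; camera adjusted p = 0.00526, adjusted p = 0.31 with an estimated correlation), led by Bhlhe41 (-2.91 ± 0.64), while 2 rose. Of 15 hepatocyte markers 8 fell, in both counts, with Serpina3k (-5.35 ± 0.63) and the asialoglycoprotein receptor genes Asgr1 (-4.78 ± 0.34) and Asgr2 (-4.30 ± 0.31) at the top (camera adjusted p = 0.00119, adjusted p = 0.31 with an estimated correlation). Alb had 80260 ± 24940 and 71370 ± 2469 CPM (adjusted p = 0.68). Its share of unscaled counts was 4.9% to 8.3% in control vehicle and 7.0% to 8.8% in Hnf4aLKO vehicle libraries, so its direction depends on the scaling. Major urinary protein genes held 6.5% to 14.2% of counts in control vehicle and 1.1% to 2.2% in Hnf4aLKO vehicle libraries, and 6 of 13 mitochondrially encoded genes fell, with mt-Cytb (-1.16 ± 0.25) first (7 adjusted over the list alone; camera adjusted p = 0.00235, adjusted p = 0.431 with an estimated correlation).

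Proliferation and p53 genes rose. Of 25 cell cycle genes 10 rose (12 adjusted over the list alone; camera adjusted p = 8.98e-05, adjusted p = 0.431 with an estimated correlation). The list mean (log2) was 0.15, 0.03 and 1.47 in control vehicle replicates 1, 2 and 3 and 1.62 to 2.51 in Hnf4aLKO vehicle libraries. The cyclins Ccnb2 (3.97 ± 0.48) and Ccnd1 (3.69 ± 0.56) changed most. Of 22 p53 target and cell death genes 11 rose and 2 fell (12 and 2 adjusted over the list alone; camera adjusted p = 0.00235, adjusted p = 0.307 with an estimated correlation). Gadd45b (4.76 ± 0.43) and Phlda3 (4.75 ± 0.37) changed most. Cdkn1a, the cell cycle inhibitor p21, rose by 3.91 ± 0.86, and by 6.65 without control vehicle replicate 2. Of 22 glutathione and NRF2 target genes 8 rose and 2 fell, in both counts, with Gstm3 (5.4 ± 0.38) and Gstm1 (3.16 ± 0.27) first (camera adjusted p = 0.0258, adjusted p = 0.307 with an estimated correlation), and this list call ended without Hnf4aLKO vehicle replicate 2 (0.0509). Fetal and dedifferentiation genes rose in 5 of 18 cases, with Sox9 first (2.08 ± 0.54; 3.26 without control vehicle replicate 2), and adjusted over the list alone 5 were higher and 2 lower (camera adjusted p = 0.016, adjusted p = 0.431 with an estimated correlation; 0.181 without control vehicle replicate 1). Their mean (log2) was 3.53 in control vehicle replicate 3, within the 3.45 to 3.73 of Hnf4aLKO vehicle libraries, and 2.31 and 2.71 in replicates 1 and 2. Of 11 bile duct markers 6 rose (8 adjusted over the list alone; camera adjusted p = 0.0028, adjusted p = 0.307 with an estimated correlation), with Tff2 (2.76 ± 0.83; 1.51 and adjusted p = 0.176 without Hnf4aLKO vehicle replicate 3) and Sox9 first. Of 15 endothelial markers 6 rose, in both counts, with Vwf (1.00 ± 0.22) and Pecam1 (0.91 ± 0.23) first (camera adjusted p = 0.0044, adjusted p = 0.458 with an estimated correlation). The Vwf call ended with a transcript length offset (adjusted p = 0.205, range over alternatives 0.000325 to 0.205). Of 36 ribosomal protein genes 3 rose by up to 0.75, which adjusted over the list alone became 0 (edgeR; median 0.41, camera adjusted p = 0.000311, adjusted p = 0.623 with an estimated correlation, fry 0.109).

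Before tunicamycin, ER stress genes moved both ways with deletion, and camera called no ER stress list with all libraries. Of 22 ER chaperone genes 4 rose and 1 fell, in both counts, with Pdia5 (-2.30 ± 0.22) and Pdia6 (0.93 ± 0.21) first. The median was -0.11, camera's direction was up (adjusted p = 0.759), and the median turned to 0.07 with upper-quartile scaling and 0.48 on the TPM scale. Of 18 genes of ER-associated degradation 4 rose and 4 fell, in both counts, from Derl3 (2.88 ± 0.46) to Fam8a1 (-1.08 ± 0.17). Their median was -0.14 (0.05 with upper-quartile scaling, 0.51 on the TPM scale) and their mean 0.06 (camera adjusted p = 0.873). Of 21 genes of the PERK-ATF4-CHOP arm, which follows translation arrest, 7 fell and 2 rose, in both counts (median -0.27, 0.34 on the TPM scale, camera adjusted p = 0.625). The direction rests on control vehicle replicate 2: its list mean (log2) was 3.56, against 2.56 and 2.20 in replicates 1 and 3 and 2.66 to 2.75 in Hnf4aLKO vehicle libraries, and camera's direction was up without it (adjusted p = 0.993). Atf5 (-1.81 ± 0.52) was -0.50 without it (adjusted p = 0.201, range over alternatives 0.00233 to 0.201). Asns fell (-5.08 ± 1.02; -2.62 without control vehicle replicate 2; limma-voom adjusted p = 0.0859, range over alternatives 2.38e-06 to 0.0859), Tnfrsf10b (3.27 ± 0.33) and Gdf15 (2.90 ± 0.38) rose, and Atf4 fell by 0.95 on the log2 scale (± 0.17, edgeR adjusted p = 0.000803). Of 25 ATF4-regulated amino acid genes 6 fell and 2 rose, in both counts, with Shmt2 (-2.97 ± 0.26) first (median -0.34, 0.24 on the TPM scale, camera adjusted p = 0.0948, 0.868 without control vehicle replicate 2, 0.00134 without replicate 1). Replicate 2 had the highest list mean (5.16, against 3.87 and 4.47 in the other control vehicle and 4.05 to 4.13 in the Hnf4aLKO vehicle libraries). The calls of Mthfd2 (-2.13 ± 0.59; -0.98, adjusted p = 0.145, range over alternatives 0.000664 to 0.145) and Psph (-1.11 ± 0.34; -0.64, adjusted p = 0.165, range over alternatives 0.000525 to 0.165) ended without it. Of 34 ER translocation and transport genes 2 rose and 5 fell, in both counts (median -0.15, 0.04 with upper-quartile scaling, 0.46 on the TPM scale, camera adjusted p = 0.411, 0.00253 without control vehicle replicate 1).

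Tunicamycin in control mice raised ER folding, ER-associated degradation and PERK-ATF4-CHOP genes and lowered metabolic, clotting and acute-phase genes. Hspa5, the main ER chaperone BiP, rose from 608 ± 235 (n = 3) to 16020 ± 1179 CPM (n = 4; log2 fold change 4.72 ± 0.34, edgeR adjusted p = 3.7e-07). Ddit3, which encodes CHOP, rose from 3.59 ± 1.10 to 1365 ± 393 CPM (8.57 ± 0.38, edgeR adjusted p = 2.04e-08). The ER-associated degradation gene Derl3 (9.90 ± 0.57) and the stress transcription factor gene Atf3 (8.87 ± 0.68) rose even more, followed by Nupr1 (7.05), Far1 (6.82), Creld2 (6.55), Bhlha15 (6.52), Irx3 (6.21) and Amigo3 (6.12). Hey2 had 1 count in total in control vehicle mice and a ratio of 295 (95% counting interval 52.7 to 11700). The genes that fell most were Mup15 (-7.45 ± 1.79; -4.65 without control vehicle replicate 3), Zfp750 (-5.76 ± 0.34), Olfr1129 (-5.10 ± 0.87), the carboxylesterase Ces1b (-5.04 ± 0.39) and Orm2 (-4.98 ± 1.00; -1.76 without control vehicle replicate 3). Next came Acot3 (-4.84 ± 0.76), Igsf23 (-4.81 ± 0.63), Lrtm1 (-4.52 ± 0.47), Ppargc1a (-4.39 ± 0.30), a coactivator of gluconeogenesis and mitochondrial genes, and Paqr7 (-4.38 ± 0.24). Mup15, Orm2 and Ces1b belong to families whose members share reads.

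In all, 5602 genes (42.1%) differed, 2731 higher and 2871 lower, 1283 and 1474 of them by at least 2-fold. In 4911 of the called genes the groups did not overlap. Chance gives this to 5.7% of unchanged genes, but the call itself favours it. The rising share of 48.8% became 71.6% on the TPM scale, with a shift of the median of all genes of 0.11. Upper-quartile scaling shifted that median by -0.18. Camera called 21 of 38 lists, fry 23, and camera with an estimated correlation 0 (5 at an unadjusted p under 0.05).

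Of 22 ER chaperone genes 20 rose (22 adjusted over the list alone; camera adjusted p = 1.3e-18, adjusted p = 0.226 with an estimated correlation). Creld2, Hspa5, Sdf2l1 (4.52 ± 0.22) and Pdia4 (4.51 ± 0.23) changed most. Of 18 ER-associated degradation genes 13 rose and 2 fell, in both counts (camera adjusted p = 3.48e-08, adjusted p = 0.123 with an estimated correlation). After Derl3 came Syvn1 (4.76 ± 0.24), Sel1l (4.09 ± 0.24) and Herpud1 (3.57 ± 0.22). Of 34 ER translocation and transport genes 27 rose (28 adjusted over the list alone; camera adjusted p = 1.57e-12, adjusted p = 0.482 with an estimated correlation). The KDEL receptor gene Kdelr3 (4.25 ± 0.53) changed most. Of 21 PERK-ATF4-CHOP genes 15 rose and 1 fell, in both counts (camera adjusted p = 3.48e-08, adjusted p = 0.226 with an estimated correlation), with Chac1 (5.08 ± 0.36) after Atf3, Ddit3 and Nupr1. Atf4 rose by 2.40 ± 0.17 and Trib3 by 4.98 ± 0.56. Of 25 ATF4-regulated amino acid genes 19 rose and 1 fell (19 and 2 adjusted over the list alone; camera adjusted p = 6.91e-07, adjusted p = 0.482 with an estimated correlation). The transporter gene Slc7a1 (4.67 ± 0.38) changed most. Dnajb9, an XBP1 target, rose by 3.60 ± 0.23, while Xbp1 itself had 213 ± 38.8 and 256 ± 23.1 CPM (adjusted p = 0.31). Fgf21 rose by 2.59 ± 0.81, by 6.20 without control vehicle replicate 2 and by 2.04 (adjusted p = 0.0554, range over alternatives 1.53e-05 to 0.0554) without replicate 1.

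Metabolic and secretory groups fell. Of 24 acute-phase genes 19 fell and 1 rose (20 and 1 adjusted over the list alone; camera adjusted p = 0.000206, adjusted p = 0.498 with an estimated correlation), with the serum amyloid genes Saa2 (-6.89 ± 1.47) and Saa1 (-5.54 ± 1.14) first. The fall rests on control vehicle replicates 2 and 3: the list mean (log2) was 6.31, 7.89 and 8.64 in control vehicle replicates 1, 2 and 3 and 5.63 to 6.5 in control tunicamycin libraries. Saa1 had 33.5 CPM in replicate 1, within the 9.17 to 71.55 CPM after tunicamycin. Of 25 urea cycle and amino acid genes 17 fell (20 adjusted over the list alone; camera adjusted p = 2.97e-05, adjusted p = 0.5 with an estimated correlation). Hal (-3.13 ± 0.48) and Arg1 (-2.60 ± 0.40) changed most. Of 23 coagulation genes 13 fell, in both counts, led by Fga (-1.99 ± 0.35; camera adjusted p = 8.97e-05, adjusted p = 0.493 with an estimated correlation). Of 22 apolipoprotein and lipoprotein genes 15 fell and 1 rose (17 and 1 adjusted over the list alone; camera adjusted p = 0.0002, adjusted p = 0.233 with an estimated correlation). Apoa4 (-2.65 ± 0.74) was among those that fell. Of 24 transcription factor genes of the hepatocyte network 11 fell, in both counts (camera adjusted p = 0.00136, adjusted p = 0.498 with an estimated correlation). After Ppargc1a came Nr1i3 (-3.01 ± 0.57; -1.94 without control vehicle replicate 1) and Onecut1 (-2.65 ± 0.41). Cebpa fell by 2.01 on the log2 scale (± 0.22, from 245 ± 57.1 to 60.9 ± 16.1 CPM). Of 31 nuclear respiratory chain genes 20 fell, Sdhd (-1.01 ± 0.15) most (21 adjusted over the list alone; camera adjusted p = 1.98e-05, adjusted p = 0.569 with an estimated correlation). Pericentral genes fell in 12 of 22 cases and rose in 1, in both counts, led by the WNT target Lgr5 (-2.42 ± 0.36; camera adjusted p = 0.00115, adjusted p = 0.498 with an estimated correlation). Periportal genes fell in 11 of 21 (12 adjusted over the list alone; camera adjusted p = 0.00115, adjusted p = 0.493 with an estimated correlation). Aldh1b1 (-3.22 ± 0.38) changed most. Of 13 mitochondrially encoded genes 4 fell (0 adjusted over the list alone; edgeR; median -0.44, camera adjusted p = 0.0285, adjusted p = 0.569 with an estimated correlation, up to 0.079 without single libraries).

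Fatty acid oxidation genes fell in 11 of 29 cases and rose in 1 (9 and 1 adjusted over the list alone; camera adjusted p = 0.000609, adjusted p = 0.569 with an estimated correlation). Camera called bile acid (8 of 25 lower, 2 higher; camera adjusted p = 0.0285, adjusted p = 0.569 with an estimated correlation, 0.0638 without control vehicle replicate 1) and complement genes (8 of 19 lower; camera adjusted p = 0.0268, adjusted p = 0.569 with an estimated correlation, 0.0727 without control vehicle replicate 2) lower, though most of their members did not pass. It also called female-biased (9 of 16 lower; camera adjusted p = 0.0317, adjusted p = 0.238 with an estimated correlation, 0.0528 without control tunicamycin replicate 3) and hepatocyte genes (8 of 15 lower; camera adjusted p = 0.0121, adjusted p = 0.498 with an estimated correlation, 0.0776 without control vehicle replicate 2) lower. These 4 lists had the same counts over the list alone. The sterol transporter gene Abcg8 (-2.29 ± 0.35), complement Hc (-1.5 ± 0.27) and the steroid enzyme gene Cyp17a1 (-3.74 ± 0.78) were among the genes that fell.

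Some groups split or moved with single libraries. Of 22 cholesterol synthesis genes 11 fell and 2 rose (12 and 2 adjusted over the list alone), from Idi1 (-3.59 ± 0.48) to Mvd (2.54 ± 0.53). The camera call (adjusted p = 0.0268, adjusted p = 0.66 with an estimated correlation) ended without control vehicle replicate 3 (0.292). Of 24 phase 1 genes 8 fell and 1 rose, in both counts. The one that rose was Cyp2b10 (5.01 ± 0.46), a target of the receptor encoded by Nr1i3, and the list call (camera adjusted p = 0.0267, adjusted p = 0.569 with an estimated correlation) ended without control vehicle replicate 1 (0.0863). Of 18 clock genes 9 fell, with Dbp (-3.54 ± 0.38), Hlf (-3.50 ± 0.25) and Per3 (-3.39 ± 0.49) first, and 4 rose, with Per1 (3.24 ± 0.28) first, without a camera call (9 and 5 adjusted over the list alone; adjusted p = 0.346). Of 22 p53 and cell death genes 7 rose, led by Tnfrsf12a (3.83 ± 0.37), and 5 fell (7 and 7 adjusted over the list alone). Their median of -0.06 and mean of 0.32 differ in sign, and the median was 0.17 on the TPM scale (camera adjusted p = 0.48). Cdkn1a rose by 3.59 ± 0.83, and by 6.34 without control vehicle replicate 2. The haemoglobin gene Hba-a1 of the erythroid list (3 of 6 fell, 4 adjusted over the list alone, camera adjusted p = 0.313) fell by 1.97 on the log2 scale (± 0.69) and was 0.07 without control vehicle replicate 3 (adjusted p = 0.928, range over alternatives 0.00583 to 0.928). Tfrc, the first of that list, fell by 2.41 (-1.24 without that library). The neutrophil markers S100a9 (-3.23 ± 0.78) and S100a8 (-2.76 ± 0.98), 2 of 4 measured (3 adjusted over the list alone), fell, and both calls ended without the same library (-1.98 and -1.22, adjusted p = 0.061 and 0.426, highest over their alternatives).

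**Figure D2:**
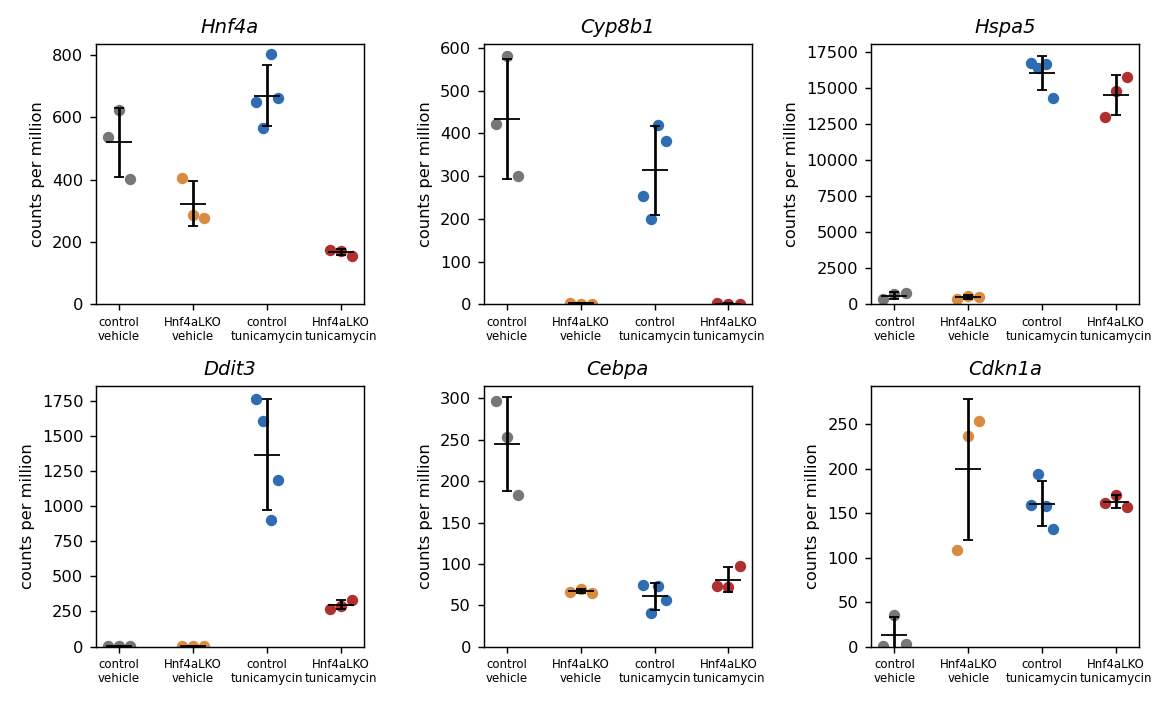
CPM of Hnf4a, Cyp8b1, Hspa5, Ddit3, Cebpa and Cdkn1a in the 4 groups, with 1 point per library and bars for the mean ± SD. Hspa5 reached 16020 ± 1179 and 14490 ± 1400 CPM after tunicamycin in control and Hnf4aLKO mice, whereas Ddit3 reached 1365 ± 393 and 297 ± 31.9.

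Tunicamycin in Hnf4aLKO mice raised the same kinds of ER genes and changed fewer genes in all (2422 against 5602; 4103 against 4939 in limma-voom with quality weights). Hspa5 rose from 494 ± 123 to 14490 ± 1400 CPM (n = 3 each, 4.87 ± 0.35, edgeR adjusted p = 1.55e-06), Ddit3 from 4.23 ± 0.91 to 297 ± 31.9 (6.13 ± 0.34, edgeR adjusted p = 1.78e-07), and Atf4 by 1.84 ± 0.17. The genes that rose most were Nupr1 (6.95 ± 0.53), C1rb, Derl3 (6.88 ± 0.49), Creld2 (6.62 ± 0.49), Ddit3, Tes (4.98 ± 0.55), Hspa5, Pdia4 (4.76 ± 0.24), Manf (4.65 ± 0.47) and the sterol esterifying enzyme Soat2 (4.63 ± 0.35). C1rb (6.94 ± 1.63; limma-voom adjusted p = 0.154, range over alternatives 1.1e-05 to 0.154) is uncertain because the sum with C1ra was 171 ± 29.2 and 163 ± 8.24. The genes that fell most included Cyp4a14 (-4.80 ± 1.09), Prok1 (-4.66 ± 0.39), Ces1b (-4.64 ± 0.42), and the glycolate oxidase gene Hao1 (-4.23 ± 0.79). Also among them were the fatty acid binding protein gene Fabp1 (-3.93 ± 0.64), Bdh1 (-3.80 ± 0.72), Slc30a10 (-3.49 ± 0.49), Apoc2 (-3.44 ± 0.59), Mroh2a (-3.44 ± 0.44) and Ces1g (-3.40 ± 0.53). Without Hnf4aLKO vehicle replicate 1, the library of its group with the most Hnf4a, the falls of Cyp4a14, Hao1, Fabp1 and Bdh1 were -2.93, -2.60, -2.54 and -2.20, and the Cyp4a14 call ended in limma-voom (adjusted p = 0.11, range over alternatives 2.38e-05 to 0.11). Hnf4a itself fell by 0.95 on the log2 scale (± 0.22, edgeR adjusted p = 0.00708).

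In all, 2422 genes (18.2%) differed, 1517 higher and 905 lower, 765 and 410 of them by at least 2-fold. In 2400 of the called genes the groups did not overlap, which the call itself favours (10% by chance among unchanged genes). The rising share of 62.6% was 48% with upper-quartile scaling, which shifted the median of all genes by -0.12, and 77.9% on the TPM scale, which shifted it by 0.11. Camera called 20 of 38 lists and fry 13. With an estimated correlation camera called 1, ER-associated degradation (6 at an unadjusted p under 0.05).

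Of 22 ER chaperone genes 21 rose, in both counts (camera adjusted p = 2.52e-28, adjusted p = 0.0916 with an estimated correlation). Of 18 ER-associated degradation genes 13 rose (14 adjusted over the list alone; camera adjusted p = 5.31e-13, adjusted p = 0.0271 with an estimated correlation), and of 34 translocation and transport genes 29 rose (30 adjusted over the list alone; camera adjusted p = 1.38e-19, adjusted p = 0.288 with an estimated correlation). PERK-ATF4-CHOP genes rose in 14 of 21 cases (15 adjusted over the list alone; camera adjusted p = 5.41e-10, adjusted p = 0.103 with an estimated correlation). Trib3 (4.57 ± 0.56) and Atf3 (4.06 ± 0.55) followed Nupr1 and Ddit3. ATF4-regulated amino acid genes rose in 14 of 25 and fell in 1 (16 and 1 adjusted over the list alone; camera adjusted p = 4.43e-07, adjusted p = 0.355 with an estimated correlation). Psat1 (3.65 ± 0.86) changed most. Genes that rose in both genotypes numbered 20 of 22 ER chaperones, 13 of 18 ER-associated degradation genes, 26 of 34 translocation and transport genes and 13 of 21 PERK-ATF4-CHOP genes. Of 22 apolipoprotein and lipoprotein genes 10 fell (13 adjusted over the list alone; camera adjusted p = 2.17e-06, adjusted p = 0.0916 with an estimated correlation), Apoc2 and Apoa4 first. Apoa4 (-3.29 ± 0.89) lost its call without Hnf4aLKO vehicle replicate 1 (-1.88, adjusted p = 0.117, range over alternatives 0.0021 to 0.117) and without each Hnf4aLKO tunicamycin library. Of 29 fatty acid oxidation genes 6 fell, with Cyp4a14 and Fabp1 first (10 adjusted over the list alone; camera adjusted p = 6.24e-05, adjusted p = 0.575 with an estimated correlation, fry 0.0998). Of 24 hepatocyte transcription factor genes 9 fell, in both counts (camera adjusted p = 0.000823, adjusted p = 0.426 with an estimated correlation), while Cebpa had 67 ± 2.50 and 80.9 ± 14.8 CPM (adjusted p = 0.472). Of 13 mitochondrially encoded genes 5 fell (10 adjusted over the list alone; camera adjusted p = 2.17e-06, adjusted p = 0.342 with an estimated correlation), and their share of counts was 6.9% to 8.1% before and 3.8% to 5.4% after tunicamycin.

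Camera called complement genes (7 of 19 lower, 1 higher; 8 and 1 adjusted over the list alone; camera adjusted p = 0.000889, adjusted p = 0.426 with an estimated correlation) and coagulation genes (6 of 23 lower, 7 adjusted over the list alone; camera adjusted p = 0.000744, adjusted p = 0.456 with an estimated correlation, fry 0.0536) lower. It also called male-biased (6 of 20 lower, 7 adjusted over the list alone; camera adjusted p = 0.00128, adjusted p = 0.355 with an estimated correlation) and periportal genes (5 of 21 lower; 6 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.00189, adjusted p = 0.426 with an estimated correlation, fry 0.0536) lower. In each of these lists most members did not pass. Hrg (-1.60 ± 0.32) and Hc (-1.25 ± 0.30) were among the genes that fell. The falls of C8a (-2.53 ± 0.55) and F13b (-2.60 ± 0.59) were -1.23 and -1.46 without Hnf4aLKO vehicle replicate 1.

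Of 16 Kupffer cell and macrophage markers edgeR called 0 (1 lower at an unadjusted p under 0.05; median -0.57, camera adjusted p = 0.045, adjusted p = 0.659 with an estimated correlation). The most abundant were Cd5l (-0.88, adjusted p = 0.252) and Clec4f (-0.65, adjusted p = 0.255), and the camera call ended without several single libraries. T and NK cell markers (5 measured, median -0.08, 0.02 on the TPM scale, camera adjusted p = 0.876), B cell markers (7 measured, median -0.54, camera adjusted p = 0.0687) and stellate cell markers (15 measured, median -0.06, 0.17 on the TPM scale, camera adjusted p = 0.795) were not called as lists. Camera called hepatocyte markers (3 of 15 lower, 1 higher; 4 and 2 adjusted over the list alone; median -0.62, camera adjusted p = 0.0285, adjusted p = 0.457 with an estimated correlation, fry 0.0633, up to 0.076 without single libraries). It also called endothelial markers (15 measured, median -0.41, camera adjusted p = 0.0446, adjusted p = 0.642 with an estimated correlation, fry 0.24, up to 0.136 without single libraries), of which edgeR called 0 (2 lower at an unadjusted p under 0.05).

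Under tunicamycin, Hnf4aLKO livers had lower levels of lipoprotein, complement, drug metabolism and male-biased genes, as under vehicle, and of part of the PERK-ATF4-CHOP arm. Ddit3 was lower by 2.20 ± 0.27 on the log2 scale (edgeR adjusted p = 3.43e-05), Atf4 by 1.5 ± 0.16 (adjusted p = 1.06e-05) and Herpud1 by 1 ± 0.20 (adjusted p = 0.00126). For each of the 3, every Hnf4aLKO library lay below every control library. Hspa5 differed by -0.14 ± 0.28 (adjusted p = 0.719) and Dnajb9 by -0.39 ± 0.20 (adjusted p = 0.142), and neither passed. The genes that fell most were Cyp2c54 (-8.67), the organic anion transporter gene Slc22a7 (-8.52), Cyp2d40 (-8.40), Cyp2c50 (-8.19), the tryptophan breakdown gene Haao (-8.08), Cyp2a12 (-8.00), Hsd3b5 (-7.94), Hao1 (-7.86) and Cyp4a14 (-7.77), and Ido2 was lower by a ratio of 382 (95% counting interval 130 to 1850). The genes that rose most were the Amy2a2, Amy2a3 and Amy2a4 copies (ratio 1460, 261 to 57600), Pnliprp1 (9.49 ± 0.51), Amy2a5 (ratio 272, 92.7 to 1320; limma-voom adjusted p = 0.0605, range over alternatives 0.00166 to 0.0605), Sorcs2 (7.85), Slc2a4 (7.74), Atp1b2 (6.94), Slc22a26 (6.88) and Lhx6 (6.80 ± 0.29).

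In all, 5157 genes (38.8%) differed, 2555 higher and 2602 lower, 1350 and 1098 of them by at least 2-fold. In 4892 of the called genes the groups did not overlap, which the call itself favours (5.7% by chance among unchanged genes). The rising share of 49.5% was 66.9% with upper-quartile scaling and 84.6% on the TPM scale, with shifts of the median of all genes of 0.20 and 0.31. Camera called 17 of 38 lists, fry 22, and camera with an estimated correlation 0 (3 at an unadjusted p under 0.05). Of the genes called under vehicle, 1166 were higher and 1335 lower by deletion under both treatments, where independent lists would share 327 and 431. The 2 comparisons share no library.

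Of 21 PERK-ATF4-CHOP genes 11 were lower and 2 higher in Hnf4aLKO mice, in both counts (median -0.84, camera adjusted p = 0.00113, adjusted p = 0.451 with an estimated correlation). Atf3 (-3.42 ± 0.49), Chac1 (-3.24 ± 0.31), which degrades glutathione, and the mTOR inhibitor gene Ddit4 (-2.31 ± 0.24) fell, and the death receptor gene Tnfrsf10b rose (2.84 ± 0.28). Trib3 (-1.57 ± 0.47) lost its call without each Hnf4aLKO tunicamycin library (adjusted p = 0.0536 to 0.057, range over alternatives 0.000276 to 0.057). Of 25 ATF4-regulated amino acid genes 9 fell, in both counts, led by Shmt2 (-2.71 ± 0.24) and Slc7a1 (-2.67 ± 0.32; camera adjusted p = 0.00161, adjusted p = 0.633 with an estimated correlation). Of 22 ER chaperones 1 rose and 1 fell, Sil1 (0.55 ± 0.17) and Pdia5 (-0.55 ± 0.20), and adjusted over the list alone edgeR called 0. Their median was -0.01 (0.17 with upper-quartile scaling, 0.45 on the TPM scale) against an upward camera direction (adjusted p = 0.941). Both gene calls ended without several single libraries (adjusted p up to 0.0894 and 0.172). Of 18 ER-associated degradation genes 8 fell and 2 rose (11 and 2 adjusted over the list alone), with Edem2 (1.33 ± 0.16) and Herpud1 first (camera adjusted p = 0.126; median -0.39, 0.09 on the TPM scale).

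Lipoprotein genes (14 of 22 lower, 3 higher; 16 and 3 adjusted over the list alone; camera adjusted p = 1.12e-05, adjusted p = 0.0894 with an estimated correlation) and complement genes (12 of 19 lower, 1 higher, in both counts; camera adjusted p = 1.97e-05, adjusted p = 0.437 with an estimated correlation) fell as under vehicle. So did phase 1 (14 of 24 lower, 4 higher; 15 and 6 adjusted over the list alone; camera adjusted p = 0.00161, adjusted p = 0.507 with an estimated correlation) and male-biased genes (17 of 20 lower, in both counts; camera adjusted p = 5.26e-11, adjusted p = 0.0894 with an estimated correlation). Apoa2 (-5.97 ± 0.42), C8a (-7.57 ± 0.67) and Cyp4a12a (-6.86 ± 0.74) were among them. Female-biased genes rose in 9 of 16 cases and fell in 2 (10 and 2 adjusted over the list alone; median 2.65, camera adjusted p = 0.00463, adjusted p = 0.0894 with an estimated correlation). The median of the female-biased genes was 1.1 on the TPM scale. The oestrogen sulfotransferase gene Sult1e1 (6.29 ± 1.16) and Cyp2a4 (6.04 ± 0.45) changed most among them. Cell cycle genes rose in 13 of 25 and fell in 2, in both counts (camera adjusted p = 0.0156, adjusted p = 0.672 with an estimated correlation). Ccnb2 (4.18 ± 0.42) and Mki67 (3.97 ± 0.73) changed most. Of 22 p53 and cell death genes 12 rose and 3 fell (14 and 3 adjusted over the list alone; camera adjusted p = 0.00581, adjusted p = 0.444 with an estimated correlation), led by Gadd45b (5.90 ± 0.41), while Cdkn1a stood at 161 ± 25.5 and 163 ± 6.95 CPM (adjusted p = 0.985). Of 36 ribosomal protein genes 16 rose (18 adjusted over the list alone; median 0.47, camera adjusted p = 0.000153, adjusted p = 0.672 with an estimated correlation). Of 13 mitochondrially encoded genes 12 fell, in both counts (median -0.77, camera adjusted p = 2.74e-05, adjusted p = 0.444 with an estimated correlation). The first was mt-Atp8 (-1.79 ± 0.39; -1.19 without control tunicamycin replicate 4). Fetal genes rose in 10 of 18 cases, in both counts (camera adjusted p = 0.00581, adjusted p = 0.501 with an estimated correlation). Ly6d led them (4.97 ± 0.94; 2.71 without Hnf4aLKO tunicamycin replicate 3). Respiratory chain genes rose in 13 of 31 cases with 1 lower (14 and 1 adjusted over the list alone; camera adjusted p = 0.00143, adjusted p = 0.672 with an estimated correlation). Cholesterol synthesis genes fell in 8 of 22, in both counts (camera adjusted p = 0.00581, adjusted p = 0.672 with an estimated correlation). Hsd17b7 (-2.46 ± 0.32) changed most. Coagulation (median 0.05, mean -0.78, camera adjusted p = 0.26) and acute-phase genes (median 0.30, mean -0.10, camera adjusted p = 0.451) differed in sign between measures. Besides coagulation, lists that camera called under vehicle and not here included hepatocyte transcription factors (camera adjusted p = 0.271; median -0.09, 0.10 with upper-quartile scaling and 0.17 on the TPM scale), bile acid (0.124), gluconeogenesis (0.856), urea cycle (0.998), periportal (0.344) and clock genes (0.175). A missed call is not a test of a difference between the 2 treatments.

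Cell type markers moved as well. Of 15 hepatocyte markers 7 fell and 3 rose, in both counts (median -0.47, camera adjusted p = 0.0362, adjusted p = 0.63 with an estimated correlation), a call that ended without control tunicamycin replicate 3 (0.0912). Their median was -0.29 with upper-quartile scaling and -0.11 on the TPM scale. Of 11 bile duct markers 6 rose and 1 fell (7 and 1 adjusted over the list alone; median 1.40, camera adjusted p = 0.0507), and of 15 stellate cell markers 6 rose (6 higher and 1 lower adjusted over the list alone; median 0.23, camera adjusted p = 0.14). Camera called neither list. Of 15 endothelial markers 1 rose, in both counts (median 0.07, camera adjusted p = 0.815).

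**Figure D3:**
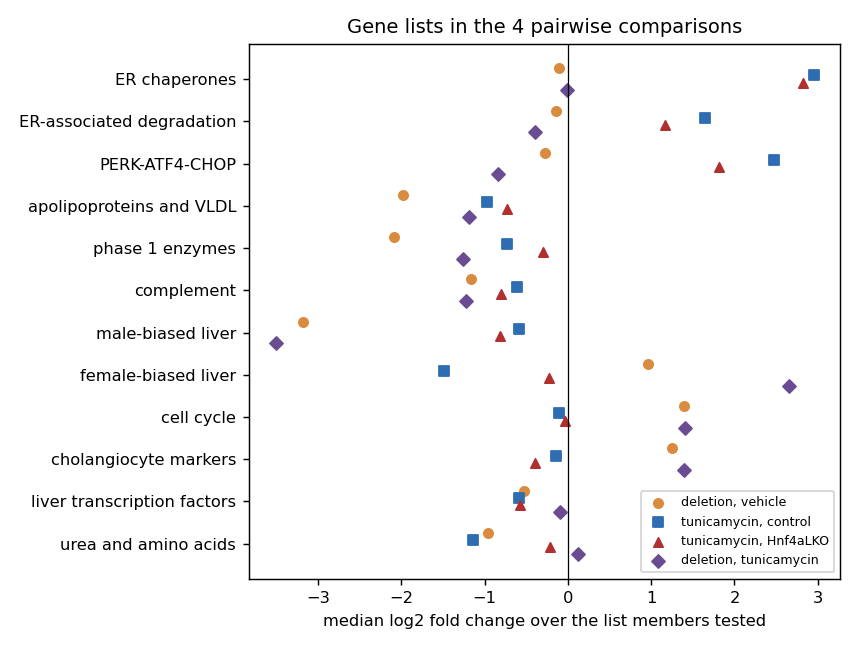
Median log2 fold change of 12 gene lists in the 4 pairwise comparisons. ER chaperone genes have medians of 2.95 and 2.82 after tunicamycin in control and Hnf4aLKO mice, and PERK-ATF4-CHOP genes 2.47 and 1.81; under upper-quartile scaling and on the TPM scale the medians of the ER chaperones between genotypes turn from negative to positive.

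The interaction asks whether tunicamycin acted differently in the 2 genotypes. Of 21 PERK-ATF4-CHOP genes 6 had a negative interaction, 1 a positive one and 14 did not pass, and the camera call of the list (adjusted p = 0.00227) ended with an estimated correlation (adjusted p = 0.916) and with fry (0.158). The negative ones included Atf3 (-4.81 ± 0.80, edgeR adjusted p = 0.00594), Chac1 (-3.27 ± 0.47), the stress hormone gene Gdf15 (-3.27 ± 0.48) and Ddit3 (-2.44 ± 0.39, adjusted p = 0.00509), while Atf4 (adjusted p = 0.181) and Trib3 (adjusted p = 0.782) did not pass. Gdf15 was already raised by deletion under vehicle, from 2.39 ± 1.87 to 17.7 ± 3.06 CPM. After tunicamycin it had 34.5 ± 6.82 CPM in control and 26.8 ± 2.63 in Hnf4aLKO mice. Cebpa fell with tunicamycin in control mice and was already low in Hnf4aLKO vehicle mice (interaction 2.28 ± 0.32, adjusted p = 0.00248), ending at 60.9 ± 16.1 and 80.9 ± 14.8 CPM. Cdkn1a took the opposite course, from 13.4 CPM in control vehicle to 200 with deletion, 161 with tunicamycin and 163 with both, and its interaction missed the threshold (edgeR adjusted p = 0.0561). The control vehicle mean of Cdkn1a rests on replicate 2, with 35.9 CPM against 1.11 and 3.04 in replicates 1 and 3. Zfp395 (3.71 ± 0.33), Zfp750 (4.36 ± 0.44), Igsf23 (7.03 ± 0.98), Rnf186 (4.05 ± 0.58), Ccn1 (3.72 ± 0.54) and the bile acid and organic anion transporter gene Slco1a4 (3.99 ± 0.73) had positive interactions, and Nrg1 (-4.67 ± 0.80), Hr (-3.91 ± 0.59), Cyp2b10 (-3.40 ± 0.57) and Prok1 (-3.27 ± 0.50) negative ones.

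Of the other named interaction genes, Scara5 (5.07 ± 0.87) lost its call in limma-voom (adjusted p = 0.0571, range over alternatives 6.14e-08 to 0.0571). C1rb (8.52 ± 1.93; limma-voom adjusted p = 0.0951, range over alternatives 0.000355 to 0.0951) is uncertain because of C1ra. Olfr1129 (4.57 ± 1.17), Nr4a1 (6.30 ± 1.35; 3.83 without control vehicle replicate 1), Cyp2a22 (-5.32 ± 1.40; -2.26 without Hnf4aLKO vehicle replicate 1), Fabp1 (-3.17 ± 0.81; -1.79 without Hnf4aLKO vehicle replicate 1), Nat8f5 (-3.16 ± 0.67) and Hnf4a (-1.31 ± 0.29) each lost their call without at least 1 single library. Their highest adjusted p over all alternatives were 0.109, 0.137, 0.699, 0.0979, 0.0541 and 0.0556. In all, 719 genes (5.4%) had an interaction, 388 positive and 331 negative. This number was 434 without Hnf4aLKO vehicle replicate 2, 434 without replicate 3, 471 without control tunicamycin replicate 2, 327 without Hnf4aLKO tunicamycin replicate 1 and 350 without replicate 2. It was 1173 in DESeq2 and 167 on the TPM scale.

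Camera called 8 lists, and with an estimated correlation 0 (adjusted p = 0.916 for each of the 8; 0 at an unadjusted p under 0.05), and fry called 0 (4 at an unadjusted p under 0.05). The PERK-ATF4-CHOP list had a median of -0.43 (7 negative and 2 positive adjusted over the list alone). Ddit4 (-2.84 ± 0.35) followed Atf3, Chac1 and Gdf15. Pericentral genes were positive in 4 of 22 cases and negative in 1 (11 and 1 adjusted over the list alone; median 0.96, camera adjusted p = 0.00023, fry 0.158). Lgr5 (1.98 ± 0.50; adjusted p up to 0.0896 without single libraries) and Rnf43 (1.97 ± 0.32) led them. Gluconeogenesis genes were positive in 3 of 18 (5 adjusted over the list alone; median 0.87, camera adjusted p = 0.00269, fry 0.158). Ppargc1a (3.19 ± 0.41) changed most. Camera also called cholesterol synthesis (median 0.91, adjusted p = 0.00545; 0.354 without control vehicle replicate 3), urea cycle and amino acid genes (0.75, 0.00482; 0.0735 without control vehicle replicate 2) and acute-phase genes (0.86, 0.0303; up to 0.354, without control vehicle replicate 3). Its last calls were respiratory chain genes (median 0.22, adjusted p = 0.0266; up to 0.282, without Hnf4aLKO vehicle replicate 1) and endothelial markers (-0.61, 0.00545; 0.0532 without control vehicle replicate 3). In these 5 lists edgeR called 1, 1, 1, 0 and 0 members (6, 7, 5, 3 and 5 at an unadjusted p under 0.05). ATF4-regulated amino acid genes were negative in 1 of 25 cases, in both counts (median -0.01, camera adjusted p = 0.156). Among ER chaperones 1 of 22 passed, Pdia5 (1.76 ± 0.29; 1 higher and 1 lower adjusted over the list alone). Their median of 0.06 turned to -0.05 with the authors' table and -0.11 on the TPM scale, and camera's direction was down (adjusted p = 0.806).

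The size of the tunicamycin response was compared between genotypes by the slope through the origin (major axis) over the genes called in control mice. Over these 5602 genes the log2 fold change in Hnf4aLKO mice rose by 0.562 per unit in control mice (jackknife SE 0.074; 0.519 to 0.596 without single libraries). Over the ER chaperones the slope was 1.02 (jackknife SE 0.0985; 0.945 to 1.07), over ER-associated degradation genes 0.777 (SE 0.0386; 0.757 to 0.799) and over PERK-ATF4-CHOP genes 0.693 (SE 0.0925; 0.608 to 0.717). Over ER translocation and transport genes it was 1.02 (SE 0.22; 0.854 to 1.15) and over ATF4-regulated amino acid genes 0.787 (SE 0.2; 0.61 to 0.861). Over the 2422 genes called in Hnf4aLKO mice it was 0.911, and over the 61 genes of the ER chaperone, ER-associated degradation and PERK-ATF4-CHOP lists 0.833. Of the called genes, 1215 rose and 679 fell in both genotypes, where independent lists would share 312 and 196, and 31 moved in opposite directions, where they would share 514.

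**Figure D4:**
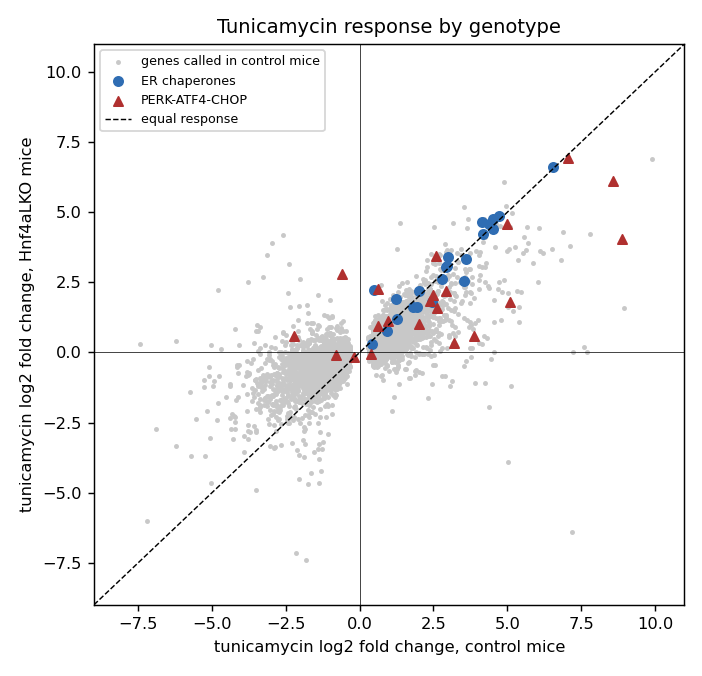
Log2 fold change of tunicamycin against vehicle in Hnf4aLKO mice plotted against that in control mice, 1 point per gene called in control mice, with ER chaperone and PERK-ATF4-CHOP genes marked and a dashed line of equal response. The slope is 1.02 over ER chaperones and 0.693 over PERK-ATF4-CHOP genes.

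Deletion and tunicamycin were also compared with each other, both against the control vehicle mice. The correlation of their log2 fold changes over 13292 genes, which are not independent replicates, was 0.230 (0.206 to 0.295 without single libraries), and simulated unchanged groups against the same controls gave 0.554 (0.529 to 0.585). The covariance was 0.316 against a simulated 0.084, a difference of 0.232. Both lowered 889 genes where independent lists would share 475, and both raised 349 where they would share 350. Deletion raised and tunicamycin lowered 367 (368), and the reverse held for 383 (452). With 3 control vehicle libraries no split leaves 2 in each part, and part of any excess may come from the shared controls. Of 22 lipoprotein genes 10 were lowered by both, of 22 cholesterol synthesis genes 9, of 25 urea cycle genes 7, of 19 complement genes 7 and of 24 hepatocyte transcription factor genes 5, Cebpa and Ppara among them.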

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

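The tests of pancreatic tissue and of amylase reads, of a lower tunicamycin dose, and of the slope over genes that deletion did not call were chosen only after the result was seen.

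In control tunicamycin mice, the only group of 4, 1 library lay far from the other 3 in 4 of 67 values tested, and chance alone gives about 1 in 20. The gap over the range was 0.862 for Hspa5, 0.897 for the mean of the male-biased genes, 0.961 for the clock genes and 0.872 for the erythroid markers. Replicate 4 was the low library for Hspa5 (14261 CPM) and the high one for the clock genes, and replicate 3, with the largest major urinary protein share of its group (15.2%), the high one for the male-biased and erythroid genes.

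The edgeR interaction, which also depends on vehicle levels, was 8.52 for C1rb, 7.03 for Igsf23, 6.30 for Nr4a1 and 5.07 for Scara5. It was 4.57 for Olfr1129, 4.36 for Zfp750, 4.05 for Rnf186, 3.99 for Slco1a4, 3.72 for Ccn1, 3.71 for Zfp395 and 2.28 for Cebpa. Negative values were -5.32 for Cyp2a22, -4.81 for Atf3, -4.67 for Nrg1, -3.91 for Hr, -3.40 for Cyp2b10, -3.27 for each of Prok1, Chac1 and Gdf15, -3.17 for Fabp1, -3.16 for Nat8f5, -2.44 for Ddit3 and -1.31 for Hnf4a. By list, camera called medians of 0.96 for pericentral, 0.91 for cholesterol synthesis, 0.87 for gluconeogenesis, 0.86 for acute-phase, 0.75 for urea cycle and 0.22 for respiratory chain genes, and of -0.43 for PERK-ATF4-CHOP and -0.61 for endothelial genes, all with adjusted p = 0.916 with an estimated correlation.

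Whether a grouping by chance could give such counts was tested by calling genes between other splits of the same libraries. For deletion under vehicle (3903 genes, highest other split 1) and tunicamycin in Hnf4aLKO mice (2422, highest other 0), 10 splits are too few, since the real split is 1 of them. For tunicamycin in control mice (5602) and deletion under tunicamycin (5157) the real split was the 1 largest of 35, with 3014 and 1562 in the next, so chance does not account for them. For the interaction (719), 2 of 100 splits, the real one included, were as large, and the highest other had 881. These splits mixed genotypes and treatments, so the large effects of deletion and of tunicamycin enter the shuffled groups. They therefore cannot decide whether chance gives the number, and they are not a check of single genes.

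Of 21 PERK-ATF4-CHOP genes 6 had a negative and 1 a positive interaction, and the slope of the tunicamycin response was lower over this list (0.693, jackknife SE 0.0925) than over the ER chaperones (1.02, SE 0.0985). Among the PERK-ATF4-CHOP genes with a negative interaction, Gdf15 was already raised by deletion under vehicle. The interaction call of the PERK-ATF4-CHOP list (camera adjusted p = 0.00227) ended with an estimated correlation (adjusted p = 0.916) and with fry (0.158). The pattern therefore holds for single genes and the slope. A lower effective dose would lower the slopes of the PERK-ATF4-CHOP and chaperone lists if both respond alike to dose. The chaperone slope stayed at 0.945 or more (lowest 0.9447) when any library was left out, above the highest of the PERK-ATF4-CHOP genes (0.717). This argues against a lower dose that acts alike on both lists. With a single dose, whether they respond alike was not measured, so a lower dose stays open. Lower depth of the Hnf4aLKO tunicamycin libraries is argued against by thinning all libraries to 15.04 M counts, after which as many members as before were called, 11 lower under tunicamycin and 6 with a negative interaction. Of 25 ATF4-regulated amino acid genes 1 had a negative and 0 a positive interaction (median -0.01, camera adjusted p = 0.156). Their slope was 0.787 (jackknife SE 0.2), and Atf4 itself did not pass (edgeR adjusted p = 0.181). A biological explanation was not tested. A need for HNF4A or for hepatocyte identity in part of the PERK-ATF4-CHOP arm is a hypothesis found on these data. A protein-level or kinetic difference, with a single time of 14 h, stays untested.

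Over the genes called in control mice, the tunicamycin response in Hnf4aLKO mice was smaller, with a slope of 0.562. With genes chosen by their call in control mice, equal responses gave slopes down to 0.941 in 20 simulations, above the observed value. The simulations took the observed folds in control mice as true and drew each gene independently, so they can understate the effect of this choice. Over the 2422 genes called in Hnf4aLKO mice the slope was 0.911, so how much comes from the choice is not settled. Genes at the floor of detection do not account for the value, since genes with at least 5 CPM in Hnf4aLKO vehicle mice gave 0.596 (0.5955). Genes that deletion had already moved in the same direction had a slope lower by 0.130 (difference -0.1298, simulated lowest -0.0997), which fits a contribution of a shared end point. Genes that deletion did not call still gave 0.569 (simulated lowest 0.9486). Such genes may have moved without a call. Whether a shared end point explains any of the smaller response therefore stays open.

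Pancreatic enzyme genes, Pnliprp1 and the Amy2a copies, were higher in Hnf4aLKO livers. Pancreatic tissue in the samples would bring its abundant transcripts, but the acinar genes Cpa1, Cpb1, Pnlip, Ctrb1 and Clps together reached at most 0.975% of the Pnliprp1 counts in any Hnf4aLKO library. Reads of Amy1 assigned to the Amy2a copies would scale with Amy1, but the Amy2a count per Amy1 count of the lowest Hnf4aLKO library was 68.5 times that of the highest control library. A biological explanation, such as a loss of repression by HNF4A in hepatocytes, was not tested.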

How the results depend on the processing

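Limma-voom with quality weights and the removal of replicate 3 of both control groups were chosen after seeing the data. No paired analysis was possible because the labels give each library its own number and no pairing of mice.

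The main counts of changed genes were 3903 for deletion under vehicle, 5602 and 2422 for tunicamycin in control and Hnf4aLKO mice, 5157 for deletion under tunicamycin and 719 for the interaction. Apart from the values that follow, they stayed within 1.5 times under the other scalings, filters and tests. With adjusted p under 0.01 they were 2268 for deletion under vehicle, 1358 for tunicamycin in Hnf4aLKO mice, 3300 for deletion under tunicamycin and 183 for the interaction; against a fold of 1.5 they were 1630, 2437 (tunicamycin in control mice), 818, 2068 and 151. Stricter thresholds give fewer genes by construction. Quality weights gave 4103 for tunicamycin in Hnf4aLKO mice, and the interaction had 1173 genes in DESeq2 and 167 on the TPM scale; the cause was not tested. Removing replicate 3 of both control groups gave 3542, 4864, 2602, 4990 and 764. Without single libraries the counts were 2824 to 3941, 4792 to 5742, 1637 to 2637, 3985 to 5457 and 327 to 833.

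With a correlation estimated from the data, camera called 0 lists for deletion under vehicle, 0 and 1 for tunicamycin in control and Hnf4aLKO mice, 0 for deletion under tunicamycin and 0 for the interaction; fry called 13 for tunicamycin in Hnf4aLKO mice and 0 for the interaction. Without single libraries the lists called were 21 to 24, 19 to 22, 16 to 22, 15 to 18 and 6 to 11. Of 3225 list values under alternatives 2975 kept their side of the threshold, 174 lost it (87 of them with the estimated correlation) and 76 passed it anew.

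The slope of the tunicamycin response was 0.911 over genes called in Hnf4aLKO mice and 0.833 (0.8327) over the fixed ER stress lists, a choice of other genes by construction, and 0.519 to 0.596 without single libraries. The correlation of deletion and tunicamycin was 0.206 to 0.295. Hnf4a on the TPM scale changed by -0.07 (-0.074) with deletion under vehicle and by 0.63 (0.632) with tunicamycin in control mice, where it passed (limma adjusted p = 0.0386); the cause was not tested. Without single libraries it ranged from -0.88 (-0.881) to -0.49 (-0.492) for deletion under vehicle and from -1.52 to -1.12 (-1.119) for the interaction, with fewer samples by construction.

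Of 12396 values of named genes under alternatives, 11671 kept their side, 688 lost it (598 without single libraries, 57 in limma-voom, 28 with a length offset, 3 with RLE scaling and 2 in DESeq2), 36 passed anew and 1 reversed: Hba-a1 with tunicamycin in control mice, from -2.46 (-2.462) to 0.07 (0.066) without single libraries. With few changed genes, simulations recovered 36% to 48% of 2-fold changes, so such changes can be missed.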

Other observations

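The tests with quality weights and without replicate 3 of both control groups were chosen only after the result was seen.

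Cyp2b9, a female-biased enzyme gene, was higher with deletion under vehicle (3.42, edgeR adjusted p = 0.0218; 6.33 without control vehicle replicate 1, and 3.00 with adjusted p = 0.0626, the highest over the alternatives, without replicate 3) and under tunicamycin (3.90, edgeR adjusted p = 0.00546). Cyp7a1, the first enzyme of bile acid synthesis, had 46.2 and 14.7 CPM in control and Hnf4aLKO vehicle mice and 45.8 ± 50.5 in control tunicamycin mice, and edgeR called it in no contrast. The fetal gene Afp fell with tunicamycin in control mice (-1.97, edgeR adjusted p = 0.00691). The glucose and lipid hormone gene Fgf21 rose with tunicamycin in Hnf4aLKO mice (3.44, edgeR adjusted p = 0.0188), a call that ended without Hnf4aLKO vehicle replicate 3 (adjusted p = 0.0768, range over alternatives 0.000151 to 0.0768).

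Mitochondrially encoded genes held 6.6% to 8.2% of counts in control tunicamycin and 3.8% to 5.4% in Hnf4aLKO tunicamycin libraries. Major urinary protein genes held 5.6% to 15.2% of counts in control tunicamycin and 1.0% to 1.4% in Hnf4aLKO tunicamycin libraries. Control vehicle libraries differed most among themselves, with replicate 3 highest in acute-phase (mean log2 8.64) and erythroid genes (7.52) and replicate 2 highest in PERK-ATF4-CHOP genes (3.56).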
